A study of Danio rerio with 15 samples.

How the data were processed

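Gene expression was measured on 15 Affymetrix Zebrafish arrays, each hybridised with RNA from zebrafish embryos. Per the labels' protocols, embryos were kept at 28 °C, RNA was taken from 20 embryos for each array, and 2 µg of total RNA was reverse transcribed with an oligo(dT) primer and amplified into biotin-labelled RNA. Because the primer binds the poly(A) tail, the signal depends on the tail as well as on the amount of a transcript. The deposited values are intensities on a linear scale with 1 value per probe set. Between 44 and 285 values per array lie below 0. How the authors summarised probes, corrected background and scaled the arrays is not given in the sources used here. No counts are involved, so the number of arrays limits the precision.

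The labels gave 6 groups. They were wild-type embryos at the 16-cell stage (n = 2), wild-type embryos at 50% epiboly (n = 1), and, with n = 3 each, uninjected wild type at 9 hours after fertilisation, uninjected MZdicer at 9 hours, wild type injected with miR-430 and MZdicer injected with miR-430. The labels state no age for the injected embryos. No group was injected without miR-430, so an effect of the injection itself cannot be told apart from one of miR-430. No label says that replicates came from separate clutches, so the p-values measure only the spread between these samples, which may be technical. No pair of arrays was identical. At most 0.0129% of probe sets had equal values on a pair of arrays. Pearson correlations of log2 values within a group ranged from 0.983 to 0.996.

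The 2% trimmed mean intensity differed between arrays, with a highest over lowest ratio of 1.11 over the 12 arrays of the 9-hour and injected groups and 1.13 over all 15. A limit of 10% had been set before the data were examined, so the linear intensities were quantile normalised, values below 0 were set to 0, and log2(intensity + 16) was analysed. A log2 change on this scale understates the change of dim transcripts. Of 15617 probe sets, 115 control probe sets were left out and 15502 were tested with no filter on dim ones. The platform annotation gave 1 gene symbol to 10795 of these, several to 135 and none to 4572. No gene was named from a probe set with several symbols. Entrez identifiers of 10711 probe sets matched the RefSeq gene table of the GRCz12tu assembly, through which 1 symbol was updated. No coordinates were used.

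Tests used R 4.3.3 and limma 3.58.1 (lmFit, contrasts.fit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all probe sets tested and calls at an adjusted p under 0.05. All adjusted p-values of single genes come from limma. The 4 groups of genotype and injection were fitted together over 12 arrays with 8 residual degrees of freedom, and gave the comparisons of MZdicer with wild type, of injected with uninjected embryos in each genotype, of injected MZdicer with uninjected wild type, and the interaction of genotype and injection. The 16-cell stage was compared with wild type at 9 hours in a fit of all 15 arrays with 9 residual degrees of freedom. Maternally supplied transcripts were those called at the 16-cell stage and at least 2-fold higher there than in wild type at 9 hours. The 13 gene lists were written before the data were examined and hold 391 symbols, of which 324 were measured. They were tested on both sides with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, each adjusted over the lists of a comparison. A gene was represented in the lists by its probe set of highest mean.

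Named genes were chosen by a rule written before the data were examined. It took the 10 largest rises and 5 largest falls among called probe sets of above-median intensity whose arrays did not overlap between groups, leaving out clone-type names, all members of the list of miR-430 targets described in other experiments, and up to 4 members of every other list with the smallest p. The interaction took 5 rises and 5 falls, without the condition on overlap, which is not defined for 4 groups. Levels are quantile-normalised intensities, given as mean ± SD over the arrays of a group. No fold is given against a group at 0.

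The fit was tested on simulated data for MZdicer against wild type over 15502 probe sets. It recovered 60 of 67 probe sets changed 1.5-fold, 67 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 17 false calls. The array information files, per the file headers, gave 3 scan days and 5 staining runs, which were used only as batch labels. Alternatives were the intensities as deposited, median centring, other pseudocounts (1 and 64), leaving out the dimmest 40% of probe sets, no mean-variance trend, the replicate number or scan day as a block, only the arrays compared, leaving out each array in turn, and other definitions of the maternal set. The staining run as a random block, an estimated correlation as an alternative for the maternal set, leave-outs for the lists and leave-outs of 16-cell and wild-type arrays for the maternal set were added after seeing the data. With the staining run as a random block, lists and the maternal set were tested with cameraPR, a form of camera applied to the moderated t values. Such a result changes both the block and the test, so a gained or lost call cannot be put down to the run. Planned tests of transcripts with a miR-430 seed site in the 3′ UTR were not run, because transcript sequences were not analysed here.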

Results

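Transcript levels were compared between wild-type zebrafish embryos and MZdicer embryos, which lack both maternal and zygotic Dicer, the enzyme that cuts microRNA precursors. Some embryos of each genotype had been injected with miR-430, a microRNA family expressed from the onset of zygotic transcription. The series title names the question as the role of miR-430 in the removal of maternal mRNAs. Uninjected wild type, uninjected MZdicer, injected wild type and injected MZdicer had 3 arrays each, the 16-cell stage had 2 and 50% epiboly had 1. Median deposited intensities ranged from 154 on a 16-cell array to 195 on an MZdicer array. Levels below are normalised intensities, mean ± SD.

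The dicer1 transcript was lower in both MZdicer groups. Deposited intensities of dicer1 were 478, 389 and 409 in uninjected wild type, 510, 510 and 543 in injected wild type, 335, 309 and 328 in MZdicer, and 265, 271 and 307 in injected MZdicer. The 16-cell arrays had 747 and 754 and the 50% epiboly array had 352. In MZdicer dicer1 fell by 0.56 ± 0.07 (SE) on the log2 scale against wild type (adjusted p = 3.43e-05). Injection left dicer1 in MZdicer at a change of -0.14 (adjusted p = 0.212). In injected wild type dicer1 was 0.26 higher (adjusted p = 0.0319), a call that was lost with the values as deposited (adjusted p = 0.0513) and under median centring (adjusted p = 0.0622). It was also lost without injected replicates 1, 2 or 3 (adjusted p of 0.0711, 0.0777 and 0.108) and without uninjected replicates 2 or 3 (adjusted p of 0.107 and 0.111). Where the probes lie relative to the mutation is not known here, so the residual signal does not test the labels.

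The comparison of 16-cell embryos with wild type at 9 hours asked which transcripts were higher early and which later. At 16 cells the germ plasm organiser buc reached 8458 ± 30.8, against 71.4 ± 0.638 at 9 hours, and the oocyte linker histone h1m reached 10750 ± 119 against 98.6 ± 8.16. The germ cell RNA-binding gene dazl stood at 4946 ± 321 against 75.3 ± 4.77, and nanos3 at 4002 ± 167 against 275 ± 20.4. The cyclin gene ccna1 reached 10288 ± 54.2 against 111 ± 11.5, and cldnd 13190 ± 154 where the 9-hour arrays were at 0. At 9 hours the keratin gene krt8 stood at 11873 ± 421 against 62.1 ± 1.20 at 16 cells. The keratin genes krt97 and krt5 and the apolipoprotein gene apoc1 were at 0 at 16 cells and at 8148 ± 297, 7476 ± 400 and 6527 ± 110 at 9 hours. Map1lc3c, pkma, birc5b, uchl1, lsm14b, org and thy1 were also among the largest declines to 9 hours, and wdr90 and lye among the largest gains.

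By list, 11 of 13 germ plasm genes were higher at 16 cells and 1 was lower (adjusted p = 9.16e-05, and 0.00910 with an estimated correlation). Of 33 oocyte and maternal cell cycle genes 26 were higher and 7 lower (adjusted p = 4.91e-05, and 0.0308 with an estimated correlation). All but 1 of 59 ribosomal protein genes were lower at 16 cells (58, adjusted p = 8.89e-26, and 0.0308 with an estimated correlation), rpl27 at 493 ± 15.2 against 7616 ± 161. Ratios of control probe sets that may depend on RNA integrity differed between the stages too, at 0.371 against 0.162 for 3′ to 5′ GAPDH, 0.453 against 0.797 for middle to 5′ GAPDH and 4.16 against 9.92 for middle to 5′ actin. The other lists lower at 16 cells were periderm (19 of 21), yolk syncytial layer and lipid transport (14 of 17), paraxial mesoderm (20 of 23), neural plate (23 of 32) and BMP and dorsoventral genes (25 of 30). Their adjusted p with an estimated correlation were 0.00274, 0.00255, 0.00274, 0.0128 and 0.0308. Examples were the dorsoventral gene ved, 8.56 ± 2.23 against 3694 ± 320, the paraxial mesoderm gene msgn1, 23.1 ± 10.4 against 4528 ± 38.3, and cdx4, 2.92 ± 1.13 against 6329 ± 11.5. The Nodal list (19 of 28 lower, adjusted p = 1.28e-04) lost its call with an estimated correlation (adjusted p = 0.0896). No shift was called for the later cell types (2 higher, 9 lower of 18, adjusted p = 0.133), the miR-430 targets (3 higher, 5 lower of 8, adjusted p = 0.398), the microRNA and decay machinery (11 higher, 5 lower of 18, adjusted p = 0.133) or p53 and stress genes (6 higher, 12 lower of 24, adjusted p = 0.231).

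In all, 11728 of 15502 probe sets differed between the stages, 6202 higher and 5526 lower at 16 cells. The higher share was 52.9% here, 45.2% with the values as deposited, 50.9% under median centring and 42.7% with the dimmest 40% of probe sets left out. The 3252 probe sets at least 2-fold higher at 16 cells form the maternally supplied set used below. Of these, 2694 (82.8%) were already at least 2-fold down on the single 50% epiboly array, which has no replicate. The 16-cell arrays and the 50% epiboly array shared 1 scan day and staining run, so this part of the change was seen within a day. No 9-hour array was scanned that day, so for the rest of the maternal set stage and day cannot be told apart.

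MZdicer was compared with wild type at 9 hours to see which transcripts change without Dicer. Among the largest rises were those of tdrd6a, a Tudor-domain gene of the germ plasm, from 97.7 ± 8.57 in wild type to 1010 ± 39.4 in MZdicer (log2 change 3.17 ± 0.13 SE, adjusted p = 1.34e-09), the superoxide dismutase gene sod1 from 278 ± 21.3 to 1856 ± 44.4, the RNA-binding gene caprin2 from 240 ± 13.9 to 1522 ± 57.9, and the malic enzyme gene me3 from 234 ± 21.5 to 1308 ± 54.3. The amino acid oxidase gene dao.1 (2.92) and mat1a (2.91) ranked after tdrd6a among the named genes by log2 change, and further rises were in the AMP deaminase gene ampd2b (2.40), nme2b.2 (2.27) and gamt (2.23). The chemokine gene cxcl12a, which guides migrating germ cells, rose from 188 ± 32.7 to 1025 ± 40.8. The largest falls were in tp53inp2a, from 986 ± 42.1 to 132 ± 7.47, the NADPH oxidase subunit gene cyba, from 1254 ± 134 to 205 ± 5.08, the heat shock factor gene hsf1 (-2.39), the replication gene lrwd1 (-2.32) and slc22a31 (-2.05).

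**Figure D1:**
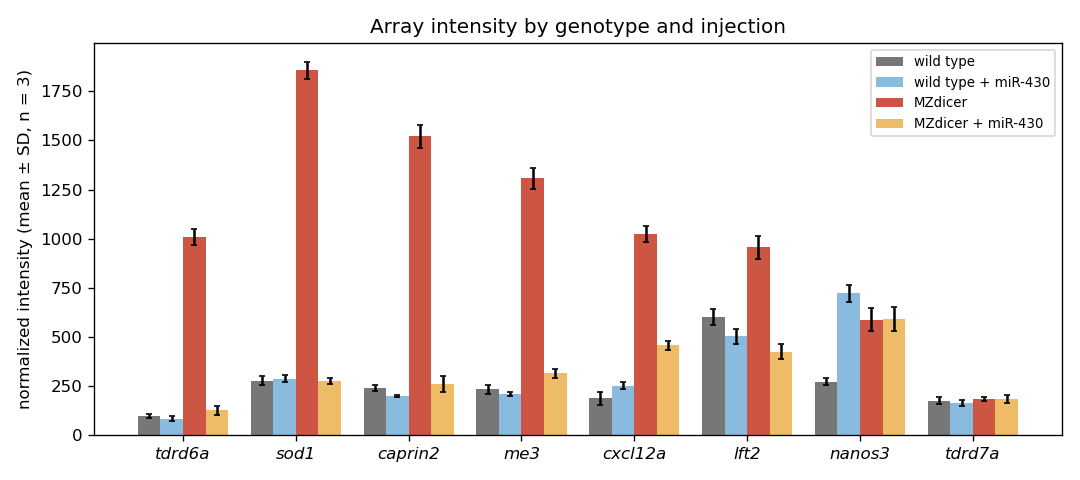
Normalised array intensity (vertical axis, linear scale) of 8 genes in wild type, injected wild type, MZdicer and injected MZdicer, as bars of the mean with SD over 3 arrays. The genes tdrd6a, sod1, caprin2 and me3 stand high in MZdicer and low in the other groups, for sod1 1856 in MZdicer against 276 in injected MZdicer, while nanos3 stands at 722 in injected wild type and tdrd7a at 184 in MZdicer against 177 in wild type.

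Among the 8 miR-430 targets described in other experiments, 5 were higher in MZdicer, 2 lower and 1 not called, with the same counts when adjusted over the list alone (list adjusted p = 0.0604, with 0.0250 under median centring and 0.0139 with the staining run as a random block and cameraPR). The higher ones were cxcl12a, nanos3 (1.06), the Nodal antagonist gene lft2 (0.65), dazl (0.56) and the chemokine receptor gene ackr3b (0.47). The lower ones were the related antagonist gene lft1 (-0.65) and the Nodal ligand gene ndr1 (-0.24, adjusted p = 0.0268), whose call was lost with the values as deposited (log2 change -0.10, adjusted p = 0.386) and without MZdicer replicate 1 or 2 or wild-type replicate 3 (adjusted p of 0.0508, 0.0920 and 0.0920). The gene tdrd7a stood at 184 ± 10.7 against 177 ± 15.9 (adjusted p = 0.683). The Nodal and mesendoderm list was lower, with 5 of 28 genes higher and 17 lower (adjusted p = 0.0447). This call was lost with an estimated correlation (adjusted p = 0.503). It was also lost without MZdicer replicate 3 (adjusted p = 0.0578), wild-type replicate 3 (0.0739), injected MZdicer replicate 2 (0.0522) or injected wild-type replicate 1 (0.0522) or 3 (0.0501). The Nodal co-receptor gene tdgf1 fell from 1718 ± 106 to 829 ± 27.03, the endoderm gene sox32 from 1075 ± 71.5 to 497 ± 4.09, and the organiser gene gsc from 743 ± 32.5 to 332 ± 22.7.

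No other list was called in this comparison at the preset correlation. BMP and dorsoventral genes had 5 of 30 higher and 12 lower (adjusted p = 0.182), among them the antagonist gene chrd (-0.99) and, in the other direction, szl (1.20). Periderm genes had 2 of 21 higher and 10 lower (adjusted p = 0.0576), with klf17 at -1.11, and this list was called with the values as deposited (adjusted p = 0.00649), under median centring (0.00104), with the staining run as a random block and cameraPR (0.0406) and without wild-type replicate 1 (0.0306) or injected MZdicer replicate 1 (0.0473). Germ plasm genes had 5 of 13 higher and 2 lower (adjusted p = 0.343), with ddx4 at -1.10 and nanos3 at 1.06. Oocyte and maternal cell cycle genes had 6 of 33 higher and 13 lower (adjusted p = 0.167, and 0.0242 under median centring), with cdc20 at -0.94 and ccnb2 at 0.76. Paraxial mesoderm genes had 6 of 23 higher and 7 lower (adjusted p = 0.444), with the Delta ligand gene dlb at 1.87. Neural plate genes had 12 of 32 higher and 8 lower (adjusted p = 0.2004), with sox11a at 1.28 and rx3 at -0.90. Yolk syncytial layer and lipid transport genes had 7 of 17 higher and 6 lower (adjusted p = 0.368), with apoa2 at 1.25 and hnf4a at -1.31, the latter not called on its other probe set. MicroRNA and decay machinery genes had 9 of 18 higher and 4 lower (adjusted p = 0.2004), with the deadenylase gene cnot7 at 1.62 and the decapping gene dcp1a at 1.07. Stress genes had 4 of 24 higher and 10 lower (adjusted p = 0.321), with the chaperone gene hspa5 at -0.96 and atf3 at 1.15. Later cell types had 0 of 18 higher and 5 lower (adjusted p = 0.2004). Ribosomal protein genes had 15 of 59 higher and 2 lower (adjusted p = 0.0576), and were called lower under median centring (adjusted p = 8.99e-05). They were called higher without wild-type replicate 1 (0.00872), MZdicer replicate 1 (0.0438) or injected MZdicer replicate 1 (0.0473).

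Over all probe sets 7344 of 15502 were called, 3444 higher and 3900 lower, and 1624 and 1014 of them changed at least 1.5-fold. With the values as deposited 2132 were at least 1.5-fold higher and 644 lower, with the dimmest 40% of probe sets left out 1041 and 770, and with a pseudocount of 64, 1180 and 674. The split depends on scaling, since 46.9% of the calls were higher in MZdicer here and 65.0% with the values as deposited, and 40.6% under median centring. The median of all log2 changes was -0.07, against 0.03 as deposited and -0.12 under median centring. With scan day as a block 7487 were called. No staining run held both MZdicer and uninjected wild-type arrays.

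Injection of miR-430 into MZdicer was compared with uninjected MZdicer to see which of these changes were reversed after injection. Without a control injection, miR-430 and the injection itself cannot be told apart. The 4 genes with the largest falls were also among those that had risen most without Dicer. Tdrd6a went from 1010 ± 39.4 to 126 ± 22.6 (log2 change -2.86 ± 0.13 SE, adjusted p = 8.65e-09), sod1 from 1856 ± 44.4 to 276 ± 15.4, caprin2 from 1522 ± 57.9 to 261 ± 39.5, me3 from 1308 ± 54.3 to 315 ± 21.9, followed by fam168a from 757 ± 35.4 to 186 ± 16.1, which 2 of its 3 other probe sets matched. The largest rises were in tp53inp2a, from 132 ± 7.47 to 660 ± 277, the hyaluronan receptor gene cd44a, from 79.4 ± 1.42 to 414 ± 227, and the cell death gene bida, from 137 ± 31.8 to 485 ± 448. The bida change of 1.37 dropped to 0.68 without injected replicate 1, and its call was lost without MZdicer replicate 2 (adjusted p = 0.0697) or 3 (adjusted p = 0.0837). The ribosome biogenesis gene tsr1 rose from 669 ± 28.4 to 1729 ± 81.7, the steroid dehydrogenase gene hsd3b2 from 999 ± 89.7 to 2522 ± 112, the sugar transporter gene slc2a8 from 212 ± 19.8 to 558 ± 72.9 and cyba from 205 ± 5.08 to 531 ± 93.8. Serpina1l (1.14), itpkcb (1.12) and drl (1.06) rose as well, as log2 changes.

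Of the 8 described miR-430 targets 0 rose, 3 fell and 5 were not called, with the same counts when adjusted over the list alone. Cxcl12a went from 1025 ± 40.8 to 457 ± 22.2, lft2 from 957 ± 59.4 to 424 ± 37.7 and ackr3b from 1211 ± 117 to 863 ± 101. Log2 changes of those not called were 0.30 for lft1, -0.24 for dazl, -0.10 for ndr1, 0.01 for nanos3 and -0.01 for tdrd7a. The dazl change was called without injected replicate 2 (log2 change -0.39, adjusted p = 0.0180). The list was lower (adjusted p = 0.0409), a call lost with an estimated correlation (adjusted p = 0.250). The Nodal list was higher (11 of 28 rose and 2 fell, adjusted p = 0.0348), with tdgf1 at 0.80 and foxa2 at 0.60, as was the BMP list (11 of 30 rose and 2 fell, adjusted p = 0.0348), with bmp2b at 0.51, the antagonist gene nog1 at 0.64 and szl at -0.85. With an estimated correlation both had an adjusted p of 0.564. The calls of the targets and of the BMP list were also lost without injected replicate 2 (adjusted p of 0.0505 for each) or 3 (0.123 for each).

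The remaining lists were not called. Yolk syncytial layer genes had 6 of 17 higher and 1 lower (adjusted p = 0.0700, with 0.0353 for the values as deposited, 0.0224 under median centring, 0.0318 without MZdicer replicate 2 and 0.0478 without injected replicate 1), neural plate genes 3 of 32 higher and 6 lower (adjusted p = 0.242), later cell types 1 of 18 higher and 0 lower (adjusted p = 0.239), and decay machinery genes 2 of 18 higher and 6 lower (adjusted p = 0.326). Ribosomal protein genes had 0 of 59 called (adjusted p = 0.326), oocyte genes 3 of 33 higher and 7 lower (adjusted p = 0.482), periderm genes 4 of 21 higher and 3 lower (adjusted p = 0.592), stress genes 3 of 24 higher and 4 lower (adjusted p = 0.592), paraxial mesoderm genes 4 of 23 higher and 4 lower (adjusted p = 0.592) and germ plasm genes 2 of 13 higher and 1 lower (adjusted p = 0.782).

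In this comparison 3815 probe sets were called, 1852 higher and 1963 lower, and at least 1.5-fold 335 higher and 691 lower. With a pseudocount of 64 these were 183 and 490, and with the dimmest 40% of probe sets left out 271 and 447. The higher share was 48.5% here, 38.6% with the values as deposited and 49.3% under median centring. All 6 arrays came from 1 staining run, within which 3104 were called from these arrays alone, but injected and uninjected MZdicer were washed on different fluidics stations. The ratio of middle to 5′ actin control probe sets was 18.2 ± 2.58 in MZdicer and 12.4 ± 0.329 in injected MZdicer. The 3′ actin control probe set read at most 196 on any array and the middle one up to 2291. The ratio is therefore no plain measure of RNA integrity. Of the 691 that fell at least 1.5-fold, 565 (81.8%) were among the 1624 higher in MZdicer than in wild type. Independent lists of these sizes would share 72.4. Simulated comparisons with no change that share the MZdicer arrays shared at most 1. Without any change almost nothing is called, so this cannot bound what the shared arrays add. In the opposite direction 186 of the 335 that rose were among the 1014 lower in MZdicer, where independent lists would share 21.9. Across probe sets, which are not independent replicates, the log2 changes in the 2 comparisons had a Pearson correlation of -0.69, where the shared arrays alone gave a simulated -0.50. Unchanged comparisons that share a group of equal size give that value by design, so it does not size the part of the correlation owed to shared arrays. The covariance was -0.118, against a simulated -0.00808. The simulated covariance is the part that independent noise of the shared arrays gives, and it is small beside the observed one. It leaves out any effect common to these arrays. The shared arrays were not split between the comparisons, so part of the excess overlap may come from them.

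**Figure D2:**
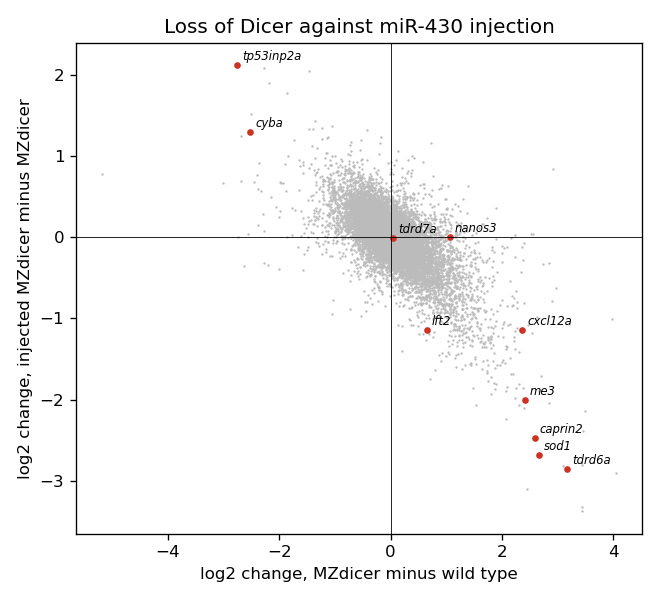
Log2 change of every probe set in MZdicer against wild type (horizontal axis) and on injection of miR-430 into MZdicer (vertical axis), with labelled genes in red. Transcripts high in MZdicer tend to lie below 0 on the vertical axis, with tdrd6a at 3.17 and -2.86 and tp53inp2a at -2.76 and 2.12, while nanos3 lies at 1.06 and 0.01. The Pearson correlation is -0.69, where simulations without change gave -0.50, a value fixed by the shared MZdicer arrays. The covariance is -0.118, against a simulated -0.00808.

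Maternally supplied transcripts were then followed through the same comparisons. The 10 with the largest falls on injection into MZdicer were tdrd6a, sod1, caprin2, me3, the clathrin adaptor gene ap2m1b (1583 ± 20.5 to 428 ± 36.0), the glutathione transferase genes gstm.1 (2650 ± 115 to 724 ± 25.1) and gstp1.2 (1072 ± 23.7 to 327 ± 68.1), the lysosomal gene laptm4a (679 ± 33.2 to 183 ± 3.09), pdcd6ip (1243 ± 39.5 to 353 ± 20.0, matched by 1 of 2 other probe sets) and the aldehyde dehydrogenase gene aldh7a1 (833 ± 56.2 to 248 ± 16.2). Of the 3252 maternal probe sets 351 (10.8%) fell at least 1.5-fold, against 340 of the 12250 others (2.78%; Fisher's exact odds ratio 4.24, p = 1.52e-70, over genes that are not independent). Most of the maternal set moved little. Its median log2 change was -0.05 against 0.05 for the others, a shift of -0.10 with camera p = 1.23e-05 at the preset correlation. With an estimated correlation p was 0.140, and without injected MZdicer replicate 2 the shift was -0.06 (p = 0.00191). The array medians of the set differed by -0.17 between injected and uninjected MZdicer (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays can give). The labels give no age for injected MZdicer, and the set was chosen for falling with age. A difference in age could therefore also lower it, which was not tested.

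In MZdicer against wild type the maternal set was shifted by 0.25 (p = 1.24e-07, and 0.0826 with an estimated correlation), where simulated unchanged groups that share the wild-type arrays gave 0.00667. The actin ratio also differed between these groups, at 18.2 in MZdicer against 9.92 in wild type. There 708 maternal probe sets (21.8%) were at least 1.5-fold higher, against 916 of the others (7.48%). Of the 708, 304 (42.9%) fell on injection, against 261 of the 916 (28.5%; Fisher's exact odds ratio 1.89, p = 1.92e-09). In injected against uninjected wild type the shift was 0.01 (camera p = 0.612, and exact permutation p = 0.6 for the array medians). At least 1.5-fold, 2.71% of the set rose against 1.76% of the others (Fisher's exact odds ratio 1.56, p = 7.81e-04). As well, 1.88% fell against 1.40% (Fisher's exact odds ratio 1.35, p = 0.0509). The set was selected for being low on the same uninjected wild-type arrays, which favours rises, and no unchanged groups were simulated for this comparison. In injected MZdicer against wild type, which uses those wild-type arrays too, the set was still shifted by 0.12 (camera p = 0.00134, and 0.263 with an estimated correlation), with 9.04% against 4.38% at least 1.5-fold higher. Its shift in the interaction was -0.13 (camera p = 1.48e-04, and 0.192 with an estimated correlation).

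**Figure D3:**
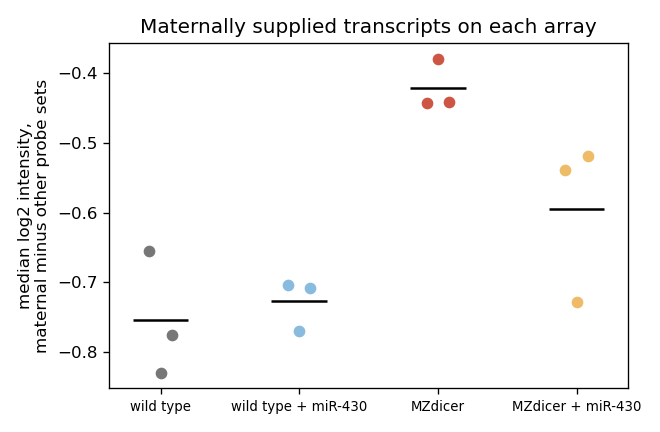
Median log2 intensity of the maternal probe sets minus that of all others on each of the 12 arrays (vertical axis), by group, with points for arrays and bars for group means. MZdicer arrays lie from -0.44 to -0.38 and injected MZdicer arrays from -0.73 to -0.52, where replicate 2 is the lowest.

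Injected MZdicer was set against uninjected wild type to see what remained changed. The gene dao.1 stood at 710 ± 288 against 34.2 ± 7.73, ampd2b at 776 ± 57.1 against 143 ± 21.9, mat1a at 328 ± 122 against 59.4 ± 4.69 and gamt at 1420 ± 699 against 310 ± 48.0. Further rises were in mst1 (1.82), snu13a (1.78, not called on its other probe set), selenop2 (1.70), gnpda1 (1.69), apoa4b.1 (1.59) and dhrs9 (1.56), as log2 changes. The largest falls were in the annexin gene anxa1a, at 1852 ± 942 against 6881 ± 478, and in lrwd1 (-1.76), slc22a31 (-1.68), hsf1 (-1.63) and supt3h (-1.5). Of the targets, cxcl12a (1.23) and nanos3 (1.07) were still higher and lft2 (-0.49) and ndr1 (-0.34) lower, the latter not called with the values as deposited (adjusted p = 0.0528). The others, lft1, tdrd7a, ackr3b and dazl, were not called (list adjusted p = 0.603), but without injected replicate 1 lft1 (-0.58, adjusted p = 4.77e-05) and dazl (0.41, adjusted p = 0.0330) were. The dazl change was also called with the values as deposited (0.36, adjusted p = 0.03935).

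The periderm list was lower (0 of 21 genes higher and 9 lower, adjusted p = 7.50e-04, and 0.125 with an estimated correlation), with anxa1c at -0.67 and grhl1 at -0.64. The oocyte and maternal cell cycle list was lower (1 of 33 higher and 15 lower, adjusted p = 0.00187, and 0.135 with an estimated correlation), with ccna2 at -0.86 and cdc20 at -0.62. The yolk syncytial layer list was higher (8 of 17 higher and 3 lower, adjusted p = 0.0290, and 0.125 with an estimated correlation), with fabp2 at 1.20 and apoa1a at 0.59, and was not called with the values as deposited (adjusted p = 0.137), under median centring (0.120) or without injected replicate 1 (adjusted p = 0.0965). Nodal genes had 4 of 28 higher and 13 lower (adjusted p = 0.0965, with 0.0123 without injected replicate 1 and 0.0488 without wild-type replicate 1), ribosomal protein genes 9 of 59 higher and 1 lower (adjusted p = 0.131, with 0.01002 without wild-type replicate 1, and called lower under median centring with 4.75e-05), germ plasm genes 4 of 13 higher and 2 lower (adjusted p = 0.483) and stress genes 1 of 24 higher and 5 lower (adjusted p = 0.483). The decay machinery, neural plate, paraxial mesoderm, later cell type and BMP lists had adjusted p of 0.601, 0.601, 0.601, 0.679 and 0.901. In total 4854 probe sets were called, 831 higher and 524 lower at least 1.5-fold (487 and 305 with a pseudocount of 64, and 523 and 343 with the dimmest 40% of probe sets left out). The higher share was 52.1% here, 68.9% with the values as deposited and 44.2% under median centring. The middle to 5′ actin ratio was 12.1 to 12.7 on injected MZdicer arrays and 8.70 to 10.9 on wild-type arrays, while their 3′ to 5′ GAPDH ratios overlapped. Of the 1624 probe sets higher in MZdicer, 967 were within 1.5-fold of wild type after injection, while 565 fell at least 1.5-fold on injection. Over all 1624 the median log2 difference from wild type was 0.91 before and 0.49 after. The 1624 were selected for being high on the uninjected MZdicer arrays, which favours a smaller difference after injection.

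In wild type, injection of miR-430 was followed by changes of which few were shared with MZdicer. The channel gene cnga1a rose from 307 ± 248 to 1316 ± 113, nanos3 from 273 ± 19.2 to 722 ± 44.5, ampd2b from 143 ± 21.9 to 389 ± 34.3 and dao.1 from 34.2 ± 7.73 to 137 ± 51.8. Further rises were in cyp2aa4 (1.35), the retinal reductase gene dhrs3a (1.23), svbp (1.17), the dynein gene dync1li1 (1.13), the pyrimidine synthesis gene dhodh (1.13) and b9d1 (1.11), as log2 changes. The largest falls were in odf3l2a, from 350 ± 32.5 to 79.7 ± 10.7, ptgr1.1, from 361 ± 61.5 to 89.4 ± 14.9, the stress-induced gene ddit4, from 471 ± 18.3 to 174 ± 73.8, and in cyp2ad2 (-1.34) and cuedc2 (-1.34), neither called on its other probe sets.

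Of the 8 described targets 2 rose, 1 fell and 5 were not called, and 2 fell when adjusted over the list alone (list adjusted p = 0.646). Besides nanos3, cxcl12a stood at 253 ± 18.9 against 188 ± 32.7 (0.41, adjusted p = 0.0164), a call lost without wild-type replicate 3 (0.30, adjusted p = 0.0703) or injected replicate 1 (adjusted p = 0.0644) or 3 (adjusted p = 0.0633), and not made on its other probe set. Lft1 was at -0.46 (adjusted p = 0.0466), a call lost when any array of either group was left out (adjusted p from 0.0718 to 0.143). The change of lft2 was called under median centring (-0.28, adjusted p = 0.0385), with the dimmest 40% of probe sets left out (adjusted p = 0.0475) and without injected replicate 1 (-0.31, adjusted p = 0.0492). Values for lft2, dazl, ndr1, ackr3b and tdrd7a were -0.25, 0.11, 0.08, -0.08 and -0.10. The oocyte and maternal cell cycle list was lower (0 of 33 rose and 7 fell, adjusted p = 2.27e-04, and 0.192 with an estimated correlation), with the cyclin gene ccna2 at -0.61, fbxo5 at -0.49 and cdc20 at -0.34. The BMP list was lower (3 of 30 rose and 7 fell, adjusted p = 0.0477, and 0.568 with an estimated correlation), with foxi1 at -0.50, id1 at -0.26 and nog1 at 0.44. The BMP call was lost with the staining run as a random block and cameraPR (0.0554) and without injected replicate 1 (0.0969), wild-type replicate 2 (0.0975), injected MZdicer replicate 2 (0.0543) or MZdicer replicate 2 (0.0550) or 3 (0.0530). Periderm (0 of 21 rose and 5 fell), yolk syncytial layer (5 of 17 rose and 1 fell) and paraxial mesoderm genes (7 of 23 rose and 3 fell) had adjusted p of 0.0914, 0.0914 and 0.0938. The periderm list was called with the values as deposited (0.00660) and under median centring (0.00278), and the yolk syncytial layer list with the mean of a gene's probe sets (0.0460). Without wild-type replicate 1 the periderm list was called lower (0.0319) and the yolk syncytial layer and ribosomal protein lists higher (0.0455 and 0.00761). Without injected replicate 2 the periderm list was called lower and the ribosomal protein list higher (0.0235 each), and without injected replicate 3 the paraxial mesoderm list higher (0.0494). For Nodal, ribosomal protein (called lower under median centring, 0.0212) and stress genes adjusted p was 0.186, and for decay machinery and later cell types 0.650. It was 0.929 for germ plasm genes and 0.931 for neural plate genes.

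The comparison called 2193 probe sets, 1138 higher and 1055 lower, with 303 and 232 at least 1.5-fold (177 and 127 with a pseudocount of 64, and 203 and 150 with the dimmest 40% of probe sets left out). Without uninjected wild-type replicate 3 the count was 1338, and with scan day as a block it was 2049. The 3′ to 5′ GAPDH ratio was 0.186 to 0.227 on injected and 0.146 to 0.177 on uninjected wild-type arrays, while their middle to 5′ actin ratios overlapped. The higher share of 51.9% was 40.8% under median centring and 56.7% with the values as deposited. Among the 303 that rose, 176 were also higher in MZdicer, where independent lists would share 31.7. Part of the excess may come from the shared wild-type arrays. Simulated unchanged groups that share these arrays gave at most 0, which cannot bound that part, since almost nothing is called without any change. With a pseudocount of 64 the overlap was 84 of 177. Of the 691 probe sets that fell on injection into MZdicer 20 fell here, where independent lists would share 10.3, and of the 335 that rose there 22 rose here, where independent lists would share 6.55. Simulations with no change gave at most 0 for each, but almost nothing is called in them.

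The difference between the injection effects in MZdicer and in wild type was tested as an interaction. Its strongest negative values, meaning a larger fall or smaller rise in MZdicer, were in sod1 (-2.73 ± 0.10 SE, adjusted p = 8.34e-09), tdrd6a (-2.68), cnga1a (-2.36), caprin2 (-2.25) and gstp1.2 (-2.05). Its strongest positive values were in cd44a (2.48), cyba (2.02), lrwd1 (1.87), tp53inp2a (1.81) and odf3l2a (1.67). For nanos3, which rose in wild type and not in MZdicer, it was -1.34 (adjusted p = 1.55e-05). In all 3516 probe sets had an interaction, 1657 positive and 1859 negative. The MZdicer arrays shared a staining run, but no run held both injected and uninjected wild-type arrays. An effect of the run in wild type therefore enters the interaction and cannot be told apart from it. The positive share was 47.1% here, 35.1% with the values as deposited and 53.8% under median centring. By list, the BMP (10 of 30 positive and 1 negative, adjusted p = 0.00186) and Nodal genes (11 of 28 positive and 2 negative, adjusted p = 0.00776) were shifted up and the described targets down (1 of 8 positive and 3 negative, adjusted p = 0.0146). With an estimated correlation their adjusted p were 0.399, 0.399 and 0.211. The other lists had adjusted p of 0.140 for ribosomal protein, 0.170 for oocyte and for paraxial mesoderm, 0.211 for decay machinery, 0.273 for stress, 0.435 for neural plate, 0.492 for later cell type, 0.510 for periderm, 0.522 for germ plasm and 0.769 for yolk syncytial layer genes. The oocyte list was called with the values as deposited (0.0439) and under median centring (0.0153). The ribosomal protein list was called without wild-type replicate 1 (0.00854) or injected wild-type replicate 2 (0.0166), in the negative direction, and under median centring in the positive direction (0.00704).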

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

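Of the tests below, those of developmental delay, of the staining run, of the loss of miR-430 and of wild type already standing at the level of injected MZdicer were chosen only after the results were seen.

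The change after miR-430 injection differed between MZdicer and wild type for 3516 probe sets, by the interaction term of the limma fit. Staining runs are not balanced in this term, since injected and uninjected arrays shared a run in MZdicer and not in wild type. Of the wild-type arrays only injected replicate 3 was stained in the run of the MZdicer arrays. A run effect in wild type thus cannot be told apart from the interaction. Among the genes named in the injection comparisons or for the interaction, 43 had such a difference, 22 negative and 21 positive. Negative values on the log2 scale, for a larger fall or smaller rise in MZdicer, were found in the superoxide dismutase gene sod1 (-2.73), the glutathione transferase genes gstp1.2 (-2.05) and gstm.1 (-1.82) and the aldehyde dehydrogenase gene aldh7a1 (-2.04). The germ plasm gene tdrd6a had -2.68, the RNA-binding gene caprin2 -2.25, the clathrin adaptor gene ap2m1b -2.04, the lysosomal gene laptm4a -1.89, me3 -1.87, pdcd6ip -1.64 and fam168a -1.59. The chemokine gene cxcl12a had -1.55, the Nodal antagonist gene lft2 -0.89 and the BMP regulator gene szl -0.54. In another group the value came mainly from a rise in wild type. These were cnga1a (-2.36), b9d1 (-1.73), ampd2b (-1.43), the germ cell gene nanos3 (-1.34), svbp (-1.22), dhodh (-1.07), dhrs3a (-0.88) and dync1li1 (-0.80).

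Positive values were found in cd44a (2.48), cyba (2.02), tp53inp2a (1.81), hsd3b2 (1.35), tsr1 (1.32), slc2a8 (1.26) and itpkcb (1.24). Among genes with positive values that fell in injected wild type, as cyba also did, were the replication gene lrwd1 (1.87), odf3l2a (1.67), cyp2ad2 (1.60), cuedc2 (1.30), ptgr1.1 (1.25), the stress-induced gene ddit4 (0.94), the ectoderm gene foxi1 (0.85), lft1 (0.76), the cell cycle genes cdc20 (0.67) and fbxo5 (0.61), and id1 (0.19). The Nodal co-receptor gene tdgf1 had 0.99, the BMP ligand gene bmp2b 0.69 and foxa2 0.56. By list, the median interaction was 0.33 for the Nodal genes, 0.21 for the BMP genes and -0.37 for the described targets, each called at the preset correlation and not with an estimated one (adjusted p of 0.399, 0.399 and 0.211).

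On injected wild-type replicate 3, a pair of control probe sets outside the genes tested read 1481 and 191.67. The next highest arrays read 185 and 24.4, and uninjected wild type ranged from 131 to 135 and from 13.8 to 15.6. No explanation of these signals was tested.

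Of the 1624 probe sets at least 1.5-fold higher in MZdicer, 565 fell at least 1.5-fold on injection within a single staining run. A difference between runs thus cannot explain the fall, although the fluidics station differed between the injected and uninjected arrays. Simulations with no injection effect gave at most 1, but almost no fall is called in them, and independent lists would share 72.4. The fall does not show what raised these transcripts. No run held MZdicer and uninjected wild-type arrays. Run and genotype therefore cannot be told apart for their rise or for that of the remaining 1059. A difference in RNA integrity was not tested and stays open for all 1624. The 3′ to 5′ GAPDH ratio was 0.196 in MZdicer, 0.162 in wild type and 0.149 in injected MZdicer, but 0.204 in injected wild type. The ratio of middle to 5′ actin control probe sets was 18.2 in MZdicer, 9.92 in wild type and 12.4 in injected MZdicer. In both ratios MZdicer overlapped neither wild type nor injected MZdicer. The actin ratio is no plain measure of integrity, since the 3′ probe set read at most 196 and the middle one up to 2291. The GAPDH ratio has the same limit, with at most 133 for the 3′ probe set and up to 591 for the 5′ one. The median change of the 1624 on injection was -0.43, below the lowest simulated value of -0.02, so loss of miR-430 may contribute to the rise as a hypothesis found and tested on the same data. There was no control injection, and the labels give no age for injected MZdicer. A fall from the injection itself or from a difference in age was not tested and stays open. A developmental delay of MZdicer would put the median change of early-zygotic minus late-rising probe sets above that of unchanged arrays, which was 0.03. Over 27 early and 88 late probe sets it was -0.41 with a bootstrap SD of 0.276 (in a narrower late set of 11 probe sets, also tried, -0.51 with an SD of 0.453). The sign is opposite to that of a delay, but the value falls short of the bound chosen for arguing against a delay, which stays open.

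Among the 303 probe sets that rose at least 1.5-fold in injected wild type, 276 were also among the 372 called without uninjected replicate 1, the array of a separate scan day, which argues against that day as the source. The number of staining runs that held both injected and uninjected wild-type arrays was 0, so run and injection cannot be told apart. Delay of the injected embryos was not decided either, with an early minus late difference of 0.10 and a bootstrap SD of 0.159, or 0.11 with an SD of 0.269 in the narrower set. The labels give no age for injected embryos, so a difference in age is untested. A difference in RNA integrity is untested too, with 3′ to 5′ GAPDH ratios of 0.186 to 0.227 on injected and 0.146 to 0.177 on uninjected arrays.

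The 691 probe sets that fell in injected MZdicer had a median change of 0.02 in injected wild type. Of these, 45.15% had a wild-type mean in the lowest 40% of probe sets, between the bounds set before that share was seen, so too low a signal stays open. Wild type may already stand near the level of injected MZdicer, since the median of injected MZdicer minus wild type over them was 0.13, but they were selected for being low in injected MZdicer, which pulls this value down. A different response of wild-type embryos to the microRNA or to the injection itself stays open as well.

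Other splits of the 6 arrays of each comparison were counted. In each only 1 of 10 splits, the real one, gave as many calls, too few splits for a share under 0.05. The real counts were 7344 for MZdicer against wild type, 3815 for injection into MZdicer, 2193 for injection into wild type and 4854 for injected MZdicer against wild type, and the highest others were 0, 0, 1 and 0. For the interaction, 1 of 100 counted splits within genotypes, of 200 possible, gave as many calls as the real 3516. The highest other, 3478, exchanged injected and uninjected arrays in 1 genotype, which turns the difference of the injection effects into their sum and is no random regrouping. It was included by choice after its count was seen, and the highest of the rest was 2161.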

How the results depend on the processing

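The staining run as a random block, leave-outs for the lists, the estimated correlation as an alternative for the maternal set and leave-outs of arrays that define it were chosen after seeing the data. Over the alternatives, 138 values of counts and tests answering a comparison stayed within 1.5 times or on the same side of the threshold, 9 moved and 1 was weaker. Of the single genes named, 5517 values stayed, 119 lost a call, 25 gained a call, 15 uncalled ones changed sign and 2 changed sign and lost their call. Of the lists outside the stage comparison, 1088 stayed, 32 lost and 31 gained a call, 15 uncalled ones changed sign and 4 uncalled ones were called with the opposite sign. Of other counts, shares and medians 664 values stayed and 34 moved. With the dimmest 40% of probe sets left out, 361 probe sets were at least 1.5-fold higher in MZdicer and lower on injection, and with a pseudocount of 64, 105 were lower in MZdicer and higher on injection, 84 were higher in MZdicer and on injection into wild type, and 8 fell on both injections.

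A 1.5-fold condition beside the adjusted p left 2638 probe sets for MZdicer against wild type, 1026 for injection into MZdicer, 535 for injection into wild type, 1355 for injected MZdicer against wild type and 1764 for the interaction, by construction. With single arrays left out, injection into wild type gave 1338 (without wild-type replicate 3) to 2051 probe sets. Where a 16-cell array was left out, the other was assumed to vary like the other groups. The maternal shift stayed at -0.10 with an estimated correlation but lost its call (p = 0.140), and ranged from -0.13 to -0.06 with single arrays left out.

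Of the list tests outside the stage comparison 12 were called, 0 with an estimated correlation, 21 under median centring, and 8 (without injected MZdicer replicate 2) to 20 (without wild-type replicate 1) with single arrays left out. Under median centring the ribosomal protein list, not called with quantile normalisation, was called with the opposite sign. It was at -0.0836 in MZdicer against wild type, -0.0219 for injection into wild type, -0.0571 for injected MZdicer against wild type and 0.0483 in the interaction. The genes rpl7a (-0.0711, adjusted p = 0.0953) and rpsa (-0.00892, adjusted p = 0.866) changed sign in MZdicer against wild type but lost their calls. The cause was not tested.

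With the replicate number as a block, 7118, 3602, 1932, 4597, 3271 and 11565 probe sets were called in the order MZdicer against wild type, injection into MZdicer, injection into wild type, injected MZdicer against wild type, interaction and stage, and 10 list tests outside the stage comparison. Of 18 pairs of arrays from different groups with equal numbers 3 had a correlation over 0.1 (from -0.23 to 0.26), and 3 of 12 arrays correlated best with their own number. These values gave no sign that the numbers pair the arrays, but so few arrays per group cannot exclude it. The block ended the calls of the Nodal list in MZdicer (adjusted p = 0.0614), of the targets on injection into MZdicer (0.0503), and of dicer1 (0.0534) and rpl5a (0.0643) on injection into wild type, and no other call of a named gene or of a list outside the stage comparison. Tests on seed sites were not run, since no transcript sequences were used here. For other lost or gained calls the cause was not tested. Dim transcripts, near the background of the arrays, limit what can be called.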

Other observations

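Most probe sets lower at 16 cells than at 9 hours were already higher at 50% epiboly, on the single array of that stage. Of the 3005 probe sets at least 2-fold lower at 16 cells than in wild type at 9 hours, 2483 (82.6%) were at least 2-fold up on that array.

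Probe sets lower in both MZdicer and injected wild type, each against uninjected wild type and at least 1.5-fold, numbered 82, where independent lists would share 15.2. Both comparisons use the same wild-type arrays. Simulated unchanged groups gave at most 1, but almost nothing is called in them, so this cannot bound what the shared arrays add.

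The ratio of the middle to the 5′ GAPDH control probe set was 0.797 ± 0.0999 in wild type, 0.796 ± 0.149 in injected wild type, 0.948 ± 0.0754 in MZdicer and 0.894 ± 0.0627 in injected MZdicer (SD, n = 3 each). It was 0.453 ± 0.0128 at the 16-cell stage (n = 2). The same ratio for the actin acta1 control probe sets differed more between groups. It was 9.92 ± 1.11 in wild type, 9.55 ± 0.754 in injected wild type, 18.2 ± 2.58 in MZdicer, 12.4 ± 0.329 in injected MZdicer and 4.16 ± 0.0501 at the 16-cell stage. The MZdicer arrays (15.4 to 20.4) did not overlap the wild-type arrays (8.70 to 10.9), a separation that 10% of splits of 3 against 3 arrays give by chance. The 3′ to 5′ GAPDH ratio was 0.162 ± 0.0155, 0.204 ± 0.0208, 0.196 ± 0.0127 and 0.149 ± 0.0165 in the same order, and 0.371 ± 0.0819 at the 16-cell stage. The 3′ GAPDH probe set read below the 5′ one throughout, so this ratio is no plain measure of RNA integrity either.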
